A study of Mus musculus with 6 samples.

How the data were processed

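RNA sequencing measured genes in 6 mouse libraries, 3 of whole pancreas dissected at e15.5 and 3 of islets isolated with collagenase from 12-week-old wild-type mice. Per the labels' protocols, RNA was purified with RNeasy Micro columns, samples of high RNA integrity were used, libraries were made with a TruSeq RNA kit and sequencing was done on a HiSeq 2000. The labels' protocols do not state that the kit kept strand. Per the submitters' processing notes, CASAVA 1.8.2, TopHat 1.3.2, Cufflinks 1.2.1 and DESeq2, with no version, were used with the mouse genome build mm10. The read counter and the gene annotation are not given in the sources used here.

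The authors deposited 1 table with 37766 entries. Per the file headers, its 6 library columns hold a normalized signal per gene, namely read counts divided by a size factor per library as the authors' DESeq2 run made them. The same deposited table carries the authors' own mean signal, log2 fold change with its standard error, a test score, p-value and adjusted p-value per gene, of which the adjusted p-value is missing for 7164 entries. Only the authors' adjusted p-value and log2 fold change were used, for counts of calls named as theirs. The 5 other entries, named with the prefix of an htseq-count summary, held reads not assigned to a gene; they made up between 40.7 and 54.6% of the reads of a library, were left out of all tests and library totals, and stood in the table that the authors' fit was run on. Of 37761 gene names, 36971 matched GENCODE M21 on GRCm38, which is the build mm10, by name and 114 by a RefSeq synonym. A further 74 matched a duplicated name, 24 had been turned into dates and 578 were unmatched, so that 98.2% of names had an annotation. By this annotation 6797 genes were lncRNAs, 18932 were protein-coding and 12032 were of other classes. Coordinates are on GRCm38 and counted from 1.

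In every library the values were whole multiples of a single step within 0.01 reads for 100% of values, so that reads could be recovered by division. For the second islet library the step, 0.992, lies so near 1 that its values cannot be told from rounded ones by that step alone, and recovery there rests on the same arithmetic as in the other libraries. Recovered reads assigned to genes ranged from 35059950 to 47346870 per library. Intervals and floors given for low counts use these reads, cover counting error only, and take 3 reads over the group as the limit that a count of 0 allows, at a confidence level of 95%. Ratios of genes with few reads in a group carry an exact counting interval.

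The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1) with empirical Bayes moderation, on genes with at least 10 normalized counts in at least 3 libraries, comparing adult islets with embryonic pancreas with 4 residual degrees of freedom. P-values were adjusted over the 21653 genes tested by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. This test was used in place of a count model because the deposited values are normalized. Count models on the recovered reads, edgeR 4.0.16 with its quasi-likelihood test and DESeq2 1.42.0, were added after the data were seen, and called 16233 and 16360 genes. Exact permutation tests of 3 against 3 libraries cannot go below p = 0.1. The correlation of lncRNAs with the nearest protein-coding gene used bedtools 2.31.1, 10000 random pairings and 1000 bootstrap resamples. Tables were handled with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.

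Before the data were examined, 23 gene lists for the cell types and processes of the tissue, the tests, the alternatives and the rule for named genes were fixed. The rule took Paupar and Pax6, the 5 lncRNAs and 5 protein-coding genes with the steepest rise and the steepest fall among called genes without overlap between groups and with a mean of at least 100 in the higher group, of each list the 2 members called with the steepest change in the majority direction and 1 in the other, and the 5 most abundant lncRNAs of each group, in all 83 genes. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, whose p asks whether the genes of a set move on balance one way and does not compare the set with other genes. Another 22 gene families chosen by symbol were tested after the results were seen, of which 1 is not reported here. Genes that share exons with another gene, antisense genes and genes with near-identical copies (Ins1 and Ins2, the trypsins, amylases and globins) have uncertain reads, since the authors' counting could divide or drop them.

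The alternatives fixed beforehand were quantile normalization, upper quartile scaling, scaling without the 20 most abundant genes of each group, pseudocounts of 0.1 and 5, no filter, a minimum of 50 normalized counts, limma-voom, the replicate number as a block, stricter thresholds and leaving out each library in turn. Replicate libraries were compared by a chi-square of their reads over genes, which was at least 15.7 per degree of freedom within groups, so that no library was a copy of another. The steps were tested on simulated data with fixed seeds, drawn from the means and library sizes of the comparison of adult islets with embryonic pancreas. Among 21454 genes tested there, limma-trend recovered 20 of 50 genes changed 1.5-fold, 61.7% of those changed 2-fold, 85.7% of those changed 4-fold and 100% of those changed 8-fold, with 5 false calls among 21258 unchanged genes. A planted list was called and 0 of 50 random lists were. Few genes were changed in the simulated data, whereas most were called in the real data, so these recovery rates need not hold there. Simulated genes were also drawn independently, so the list result does not cover lists of correlated genes.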

Results

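Messenger RNA and long noncoding RNA (lncRNA) were profiled in the mouse pancreas at 2 ages by RNA sequencing. The 3 libraries of embryonic pancreas came from the whole organ dissected at e15.5, an embryonic stage when endocrine, exocrine and mesenchymal cells are all present. The 3 libraries of adult islets came from the endocrine islets of 12-week-old mice, freed from the organ with collagenase. Tissue, isolation and age differ together between the groups and cannot be told apart. A gene said below to rise or fall was higher or lower in the islets, which may come from any of these, the mix of cells included. Reads assigned to genes numbered 35059950, 36287602 and 39713899 in the embryonic libraries and 41983532, 47346870 and 45411891 in the islet libraries, so that a gene at 1 normalized count rested on about 1 read. Between 28713 and 32394 of the 37761 genes had at least 1 read per library. The mitochondrial ribosomal RNA gene mt-Rnr2 took between 16.4 and 19.6% of assigned reads in every library, and both insulin genes together took 0.00960 ± 0.00282% in the embryonic pancreas and 6.48 ± 0.433% in the islets. Values below are the authors' normalized counts as mean ± SD, with n = 3 per group. Fold changes are adult islets over embryonic pancreas on the log2(value + 1) scale, which understates the change of low genes. Nothing in the labels says that libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

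The lncRNA Paupar, transcribed next to the gene of the islet transcription factor Pax6, was higher in the adult islets, and so was Pax6 itself. Paupar rose from 24.2 ± 11.1 to 439 ± 57.3 normalized counts (log2 fold change 4.24, SE 0.36, limma-trend adjusted p = 6.8e-06). Pax6 rose from 1323 ± 325 to 14332 ± 259 normalized counts (log2 fold change 3.46, SE 0.15, limma-trend adjusted p = 1.2e-07). In the GENCODE M21 annotation of GRCm38, Paupar (ENSMUSG00000102424.2) is a lincRNA of 3482 bp on the minus strand of chromosome 2, 105657862 to 105661343, and it shares 0% of its exonic length with another gene. Its nearest end lies 7.557 kb before the 5′ end of Pax6 (ENSMUSG00000027168.21), which is on the plus strand of chromosome 2, 105668900 to 105697364. The antisense lncRNA Pax6os1, on the minus strand of chromosome 2, 105536080 to 105670330 and overlapping the start of Pax6, went from 25.2 ± 6.22 to 446 ± 42.6 (log2 fold change 4.11). Paupar lies wholly within the span of Pax6os1 on the same strand, so that reads of unspliced Pax6os1 RNA cannot be separated from those of Paupar. Elp4, a subunit of the Elongator complex encoded on the far side of Pax6, differed less, with a log2 fold change of 0.51. Both of these neighbours were picked for display after their values were seen. The log2 fold change of Paupar ranged over 3.80 to 4.51 and that of Pax6 over 3.34 to 3.66 when each library was left out in turn.

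**Figure D1:**
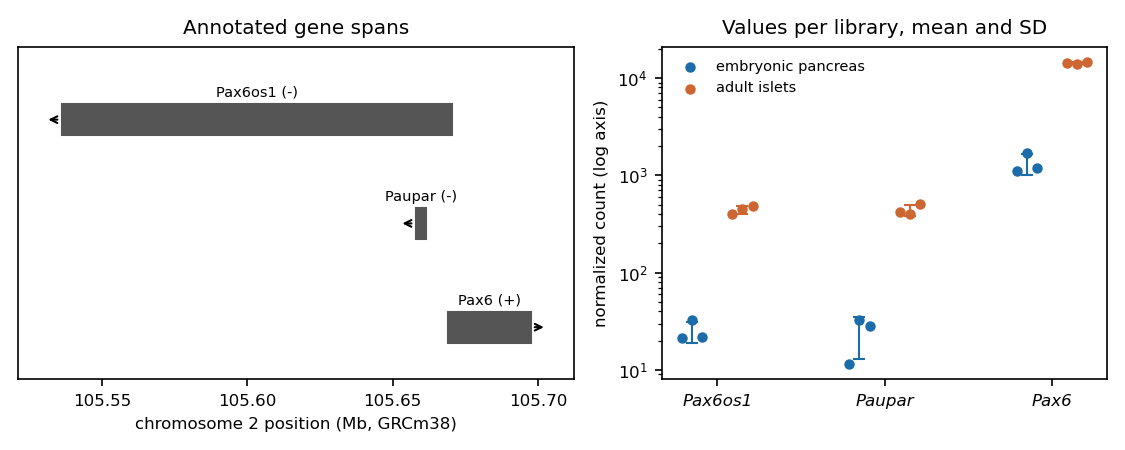
Left, annotated spans of Pax6os1, Paupar and Pax6 on mouse chromosome 2 (position in Mb, arrow in the direction of transcription); right, their normalized counts on a log axis in 3 embryonic pancreas and 3 adult islet libraries (points), with mean and SD (bars). Paupar averaged 24.2 in the embryonic pancreas and 439 in the islets, and Pax6 averaged 1323 and 14332.

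Across the genome, beta cell and secretory granule genes were higher in the islets, and cell division, erythroid and most matrix and imprinted genes were higher in the embryonic pancreas. The protein-coding genes with the steepest rises were Pdyn, which encodes the opioid precursor prodynorphin, from 2.50 ± 0.606 to 10867 ± 572, Pnlip, the pancreatic triglyceride lipase, from 33.7 ± 7.65 to 109899 ± 57333, and Ucn3, the peptide urocortin 3 of mature beta cells, from 1.36 ± 1.60 to 5146 ± 1082 (log2 fold changes 11.61, 11.53 and 11.30). Pnlip is on the list of acinar genes, and acinar cells carried along with the islets were not excluded as its source. Gsdma, a gasdermin, had 1 read in the embryonic group and averaged 3626 ± 355 in the islets (ratio 11679, 95% counting interval 2096 to 461325). Reg2, a secreted lectin of the Reg family, had no reads in the embryonic pancreas and was at least 3759-fold higher in the islets, at 7004 in the second islet library against 2370 and 1124 in the others, with log2 fold changes of 10.67 to 11.99 when each library was left out. Pnlip was likewise highest in the second islet library, at 175236 against 86467 and 67994, and carried-along acinar cells were not excluded for Reg2 either. The steepest falls were in Serpina6, the corticosteroid-binding globulin, from 22791 ± 6049.9 to 1.78 ± 0.682 (log2 fold change −13.00), and in the embryonic globin Hbb-y, which was at least 7326-fold lower in the islets.

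Of 21653 genes tested, 15770 (72.8%) differed by limma-trend at an adjusted p under 0.05, of which 7845 were higher and 7925 lower in the islets. At least a 2-fold change was seen in 10412 of them, 4890 higher and 5522 lower. Among protein-coding genes 12050 of 15471 (77.9%) differed, 6386 higher and 5664 lower, and 12120 did so adjusted over the list alone. Agtr2, the type 2 angiotensin receptor, fell from 2929.9 ± 1019 to 1 read in the islets (ratio 8167, 95% counting interval 1465 to 322598), Muc16, a mucin of mesothelium, fell from 2858 ± 654 to 1.32 ± 2.29 (log2 fold change −10.69), and the RNA-binding protein gene Igf2bp1 fell from 3654 ± 231 to 2.42 ± 2.12 (log2 fold change −10.36). Muc16 had 4 reads in the islets, all in the second library, and Igf2bp1 had 7, with none in the third, so the size of both falls is uncertain. In the authors' deposited table, 16296 genes passed the same threshold, 7767 higher and 8529 lower in the islets. The values of 16684 genes (77.1%) did not overlap between the groups, where chance gives 10%. With 3 libraries per group and 15770 genes changed, a fold change is relative to the authors' scaling. When libraries were scaled without the 20 most abundant genes of each group, the median log2 fold change of all genes moved from −0.03 to −0.26, the calls became 6636 higher and 9506 lower, and the share of protein-coding calls that were higher fell from 53.0 to 43.8%. Over all the alternatives that share ranged from 43.8 to 57.0%, and that of all genes called from 41.1 to 53.9%, so neither direction prevails regardless of scaling. The first principal component, which carried 92.2% of the variance, separated the groups, and Spearman correlations were 0.977 to 0.994 within groups and 0.776 to 0.807 between them.

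The hormone genes of beta, alpha, delta and PP cells were higher in the adult islets, while that of epsilon cells was lower. Of the beta cell list, 20 of 20 genes rose and 20 did so adjusted over the list alone, with a median log2 fold change of 4.76. Among them Ucn3 rose as given above and Ins2, which encodes insulin, rose from 1892 ± 679 to 1818620 ± 164753 (log2 fold change 9.96, SE 0.23, limma-trend adjusted p = 8.3e-09). The list stood above the other genes tested (camera adjusted p = 2.9e-10, and adjusted p = 0.417 with an estimated correlation). Its genes took 0.0532 ± 0.00873% of assigned reads in the embryonic pancreas and 9.40 ± 0.607% in the islets. Of 12 alpha cell genes, 8 rose, 3 fell and 1 was not called, with 11 called adjusted over the list alone. Gcg, which encodes glucagon, rose from 33351 ± 12656 to 995501 ± 49105 and the amino acid transporter gene Slc7a2 rose from 2109 ± 98.8 to 12069.6 ± 1193 (log2 fold changes 4.96 and 2.51), while Fap, a membrane protease encoded beside Gcg, fell from 1199 ± 126 to 48.4 ± 14.9 (log2 fold change −4.64). The alpha list as a whole did not pass by camera (adjusted p = 0.186) but did as higher by fry (adjusted p = 0.0155). Of 7 genes of delta, PP and epsilon cells, 5 rose, 2 fell and 0 were not called, with 7 called adjusted over the list alone. Sst (somatostatin) rose from 88.0 ± 20.9 to 57060.2 ± 2703 and Ppy (pancreatic polypeptide) from 86.1 ± 9.24 to 48883 ± 13698, whereas Ghrl (ghrelin) fell from 211 ± 84.1 to 68.0 ± 13.3 (log2 fold changes 9.35, 9.09 and −1.57). This list was higher by camera (adjusted p = 0.0269, and adjusted p = 0.419 with an estimated correlation), and its call also ended with a minimum of 50 normalized counts (camera adjusted p = 0.0584, in a range of 2.2e-05 to 0.419 over the alternatives).

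Most transcription factors of differentiated islet cells were higher in the islets and most of those of pancreatic progenitors were lower. Of 13 islet transcription factor genes, 11 rose, 0 fell and 2 were not called, and 11 were called adjusted over the list alone. St18 rose from 893 ± 176 to 12907 ± 516 and Neurod1, a basic helix-loop-helix factor of endocrine cells, from 480.4 ± 52.8 to 5489 ± 72.1 (log2 fold changes 3.87 and 3.52). Camera placed this list above the other genes (adjusted p = 5.7e-05, and adjusted p = 0.419 with an estimated correlation). Of 15 pancreatic progenitor genes, 3 rose and 12 fell, 0 were not called, and all 15 were called adjusted over the list alone. Onecut1, a homeobox factor of the early pancreas, fell from 834 ± 31.6 to 1.38 ± 0.518 and the nuclear receptor gene Nr5a2 from 5930.2 ± 555 to 165 ± 74.7, while Onecut2 rose from 108 ± 29.1 to 203 ± 44.4 (log2 fold changes −8.47, −5.25 and 0.92). Onecut1 shares 52.8% of its exonic length with another annotated gene, which leaves its reads uncertain, and Onecut2 was no longer called without embryonic pancreas 3 and the second islet library (log2 fold change 0.73, adjusted p = 0.0638). Camera gave an adjusted p = 7.0e-04 for the fall of the progenitor list, and adjusted p = 0.417 with an estimated correlation. Of 10 endocrine progenitor genes, 3 rose, 5 fell and 2 were not called (8 called adjusted over the list alone), and the list did not pass by camera (adjusted p = 0.279) but did as lower by fry (adjusted p = 0.00102). Pax4, a factor of beta and delta cell progenitors, went from 210.2 ± 35.7 to 3 reads over the islet libraries (ratio 197, 95% counting interval 67.2 to 959), Neurod2 was at least 85.3-fold lower in the islets, where it had no reads, and Btbd17 rose from 296 ± 95.6 to 1107 ± 64.2 (log2 fold change 1.95).

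Digestive enzyme genes of acinar cells, the exocrine cells of the pancreas, differed in both directions. Of 26 acinar genes, 17 rose, 8 fell and 1 was not called, with 25 called adjusted over the list alone and a median log2 fold change of 4.03. Besides Pnlip, Zg16, a zymogen granule protein gene, rose from 2.84 ± 1.71 to 7819 ± 3808, while Rbpjl, a transcription factor gene of acinar cells, fell from 3603 ± 669 to 30.7 ± 14.7 (log2 fold changes 10.97 and −6.91). Camera gave an adjusted p = 0.00565 for a rise of the list, and adjusted p = 0.649 with an estimated correlation. Acinar genes took 0.785, 0.887 and 0.699% of assigned reads in the embryonic libraries and 1.3, 2.59 and 0.973% in the islet libraries (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows). Reads of the trypsin, elastase and amylase families may have been divided among near-identical copies by the authors' counting, so single members are uncertain. Of 10 duct genes, 4 rose, 4 fell and 2 were not called, with 9 called adjusted over the list alone. The keratins Krt7 and Krt18 rose from 2131 ± 336 to 14309.9 ± 1527 and from 6709 ± 1342 to 21056 ± 7684, and carbonic anhydrase 2, Car2, fell from 288 ± 26.8 to 10.1 ± 3.73 (log2 fold changes 2.75, 1.61 and −4.76). Krt18, like the acinar share, was highest in the second islet library, at 29919 against 16976 and 16272 in the others. The duct list did not pass (camera adjusted p = 0.815), and its signs differed, with a median of 0.23, which turned to −0.07 under quantile normalization and −0.00 when scaled without the 20 most abundant genes, and a mean of −0.17.

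**Figure D2:**
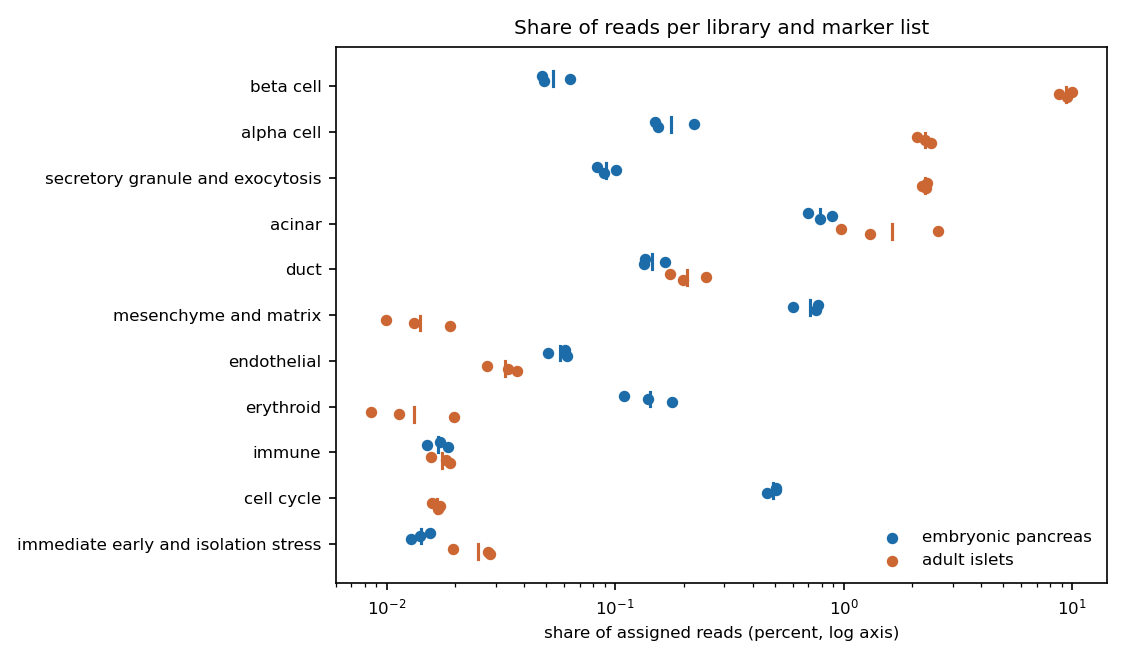
Share of assigned reads (percent, log axis) taken by each marker list in 3 embryonic pancreas and 3 adult islet libraries (points), with the group mean (vertical bar). The mesenchyme and matrix list fell from a mean of 0.711% to 0.0140%, and the second islet library stood at 2.59% for acinar genes against 1.3 and 0.973%.

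Most mesenchyme genes and all erythroid genes tested were lower in the islets. Of 22 mesenchyme and matrix genes, 2 rose, 19 fell and 1 was not called, and 21 were called adjusted over the list alone. Wt1, a transcription factor of mesothelium, fell from 1219 ± 99.7 to 1.03 ± 0.993 (3 reads in the islets, ratio 1153, 95% counting interval 394 to 5594) and the homeobox gene Barx1 from 571 ± 157 to 0.366 ± 0.634 (1 read in the islets, ratio 1602, 95% counting interval 287 to 63317), while Meox1 rose from 206 ± 15.1 to 410.4 ± 67.3 (log2 fold change 0.98). This list was lower by camera (adjusted p = 1.9e-07, and adjusted p = 0.417 with an estimated correlation) and went from 0.711 ± 0.0940 to 0.0140 ± 0.00451% of assigned reads. Of 12 erythroid genes, 0 rose, 12 fell and 0 were not called, and all 12 were called adjusted over the list alone. The embryonic globin Hba-x was at least 895-fold lower and, like Hbb-y, had no reads in the islets, and the list passed (camera adjusted p = 8.2e-05, and adjusted p = 0.276 with an estimated correlation). Of 12 endothelial genes, 1 rose, 5 fell and 6 were not called (6 called adjusted over the list alone). Vwf and Cldn5, which encode von Willebrand factor and a tight junction claudin, fell from 1275 ± 288 to 191 ± 55.4 and from 481 ± 42.9 to 78.5 ± 15.2, whereas the growth factor receptor gene Flt1 rose from 1231 ± 60.9 to 2778 ± 299 (log2 fold changes −2.75, −2.61 and 1.17). The endothelial list did not pass (camera adjusted p = 0.114) but did as lower under quantile normalization (0.0425) and by fry (0.00947).

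Immune and neural genes moved both ways. Of 16 immune genes, 6 rose, 9 fell and 1 was not called, with 15 called adjusted over the list alone. The macrophage receptor gene Adgre1 fell from 638 ± 84.7 to 122 ± 18.8 (log2 fold change −2.38) and Cd3e, part of the T cell receptor, fell from 19.6 ± 6.53 to 1 read (ratio 56.6, 95% counting interval 9.80 to 2271), while H2-Aa, an MHC class II chain, rose from 55.9 ± 13.2 to 1256 ± 100.1 (log2 fold change 4.49). The immune list did not pass (camera adjusted p = 0.815), with a median of −0.87 but a mean of 0.41, camera pointing down and fry, which asks only whether a set's genes move on balance one way, pointing up with an adjusted p = 0.0187. Over the alternatives of this list adjusted p ranged from 0.0187 to 0.995. Of 12 neural and Schwann cell genes, 4 rose, 8 fell and 0 were not called, with 12 called adjusted over the list alone. Fabp7, a lipid-binding protein of glia, fell from 309 ± 8.26 to 9.13 ± 8.38 (log2 fold change −5.71, and −6.49 to −4.43 when each library was left out) and S100b from 128 ± 22.2 to 22.3 ± 5.92 (log2 fold change −2.48), while the neuronal RNA-binding protein gene Elavl4 rose from 358 ± 41.8 to 2203 ± 114 (log2 fold change 2.62). The neural list did not pass (camera adjusted p = 0.549), and its median of −1.30 and mean of −0.79 were below 0 while fry pointed up.

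Cell division genes and most imprinted and fetal RNA-binding protein genes were lower in the islets. All 26 of 26 cell cycle genes fell, as did 26 adjusted over the list alone, with 0 higher and 0 not called, and their share of assigned reads went from 0.492 ± 0.0253 to 0.0165 ± 0.000707%. Bub1, a spindle checkpoint kinase gene, fell from 3727 ± 221 to 7.03 ± 1.71 and the mitotic cyclin gene Ccnb1 from 5761 ± 1211 to 19.6 ± 3.07 (log2 fold changes −8.88 and −8.12). Camera gave an adjusted p = 3.1e-13 for this list, and adjusted p = 0.276 with an estimated correlation. Of 17 imprinted genes, 2 rose, 15 fell and 0 were not called, with 17 called adjusted over the list alone. Cdkn1c, an inhibitor of cell division, fell from 16929 ± 1899 to 20.9 ± 5.93 and Snrpn rose from 279 ± 13.1 to 803 ± 26.6 (log2 fold changes −9.63 and 1.52), both sharing over 30% of their exonic length with another annotated gene (30.7 and 34.1%), which leaves their reads uncertain. Camera placed the imprinted list below the other genes (adjusted p = 2.7e-05, and adjusted p = 0.193 with an estimated correlation). Of 8 fetal RNA-binding and chromatin genes, 1 rose, 7 fell and 0 were not called, with 8 called adjusted over the list alone. Besides Igf2bp1, Afp, the fetal serum protein alpha-fetoprotein, fell from 1828 ± 452 to 1.36 ± 1.5 (log2 fold change −9.79), whereas Lin28a, which blocks let-7 microRNA processing, rose from 12.7 ± 4.36 to 111 ± 14.2 (log2 fold change 3.09). Camera gave an adjusted p = 0.00345 for the fetal list, and adjusted p = 0.276 with an estimated correlation.

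Genes of hormone secretion and most genes of protein folding in the endoplasmic reticulum (ER) were higher in the islets. All 21 of 21 secretory granule and exocytosis genes rose, as did 21 adjusted over the list alone, with 0 lower and 0 not called. Scg2 and Vgf, which encode granins of dense-core granules, rose from 842 ± 323 to 245453 ± 15762 and from 18.4 ± 8.52 to 3269 ± 289.8 (log2 fold changes 8.25 and 7.52). Camera gave an adjusted p = 1.3e-10 for the granule list, and adjusted p = 0.289 with an estimated correlation. Of 16 genes of ER chaperones and the unfolded protein response, 13 rose, 0 fell and 3 were not called, with 13 called adjusted over the list alone. Dnajb9, an ER co-chaperone, rose from 774 ± 136 to 14467 ± 847 and the stress transcription factor gene Ddit3 from 156 ± 15.9 to 1894 ± 124 (log2 fold changes 4.24 and 3.60). This list passed (camera adjusted p = 1.4e-04, and adjusted p = 0.419 with an estimated correlation). Of 24 oxidative phosphorylation genes, 2 rose, 7 fell and 15 were not called (9 called adjusted over the list alone). Atp5o, a subunit of ATP synthase, fell from 4873 ± 752 to 2279.8 ± 53.4 and Ndufa4 from 4559 ± 646 to 3142 ± 245, while Ndufa1, a subunit of complex I, rose from 650.0 ± 80.3 to 1834 ± 41.1 (log2 fold changes −1.08, −0.53 and 1.5). The list did not pass (camera adjusted p = 0.549), and its median of −0.07 turned to 0.03 under upper quartile scaling, but it passed as lower under quantile normalization (camera adjusted p = 0.0109, median −0.32).

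Most genes that mature beta cells keep low, known as disallowed genes, were lower in the islets, and most early response genes were higher. Of 16 disallowed genes, 0 rose, 15 fell and 1 was not called, with 15 called adjusted over the list alone. Igfbp4, which binds insulin-like growth factors, fell from 7356 ± 442 to 81.8 ± 40.3 and the glutathione transferase gene Mgst1 from 3612 ± 761 to 91.4 ± 50.8 (log2 fold changes −6.59 and −5.42). The disallowed list passed (camera adjusted p = 2.4e-06, and adjusted p = 0.417 with an estimated correlation). Of 16 immediate early and isolation stress genes, 14 rose, 1 fell and 1 was not called, with 16 called adjusted over the list alone. The chemokine gene Cxcl2 had no reads in the embryonic pancreas and was at least 26.8-fold higher in the islets, at 25 ± 3.65, Ier3 rose from 71.8 ± 7.39 to 875 ± 242, and Ier2 fell from 639.6 ± 86.2 to 333 ± 37.2 (log2 fold changes 3.55 and −0.94 for the latter pair). Camera gave an adjusted p = 6.9e-04 for these genes, and adjusted p = 0.419 with an estimated correlation. Their share of assigned reads was 0.0282, 0.0277 and 0.0195% in the islet libraries, which were isolated with collagenase, and 0.0141 ± 0.00141% in the embryonic pancreas. Over all 23 lists, 15 passed by camera with a preset correlation of 0.01 and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and 20 passed by fry. For those 15, adjusted p ranged from 7.4e-45 to 0.0584 over the alternatives that kept camera's preset correlation. At that preset, other splits of the libraries into 3 and 3 called 11 to 15 lists. The number of lists called by camera therefore does not set the real grouping apart, and its p-values above carry this limit.

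**Figure D3:**
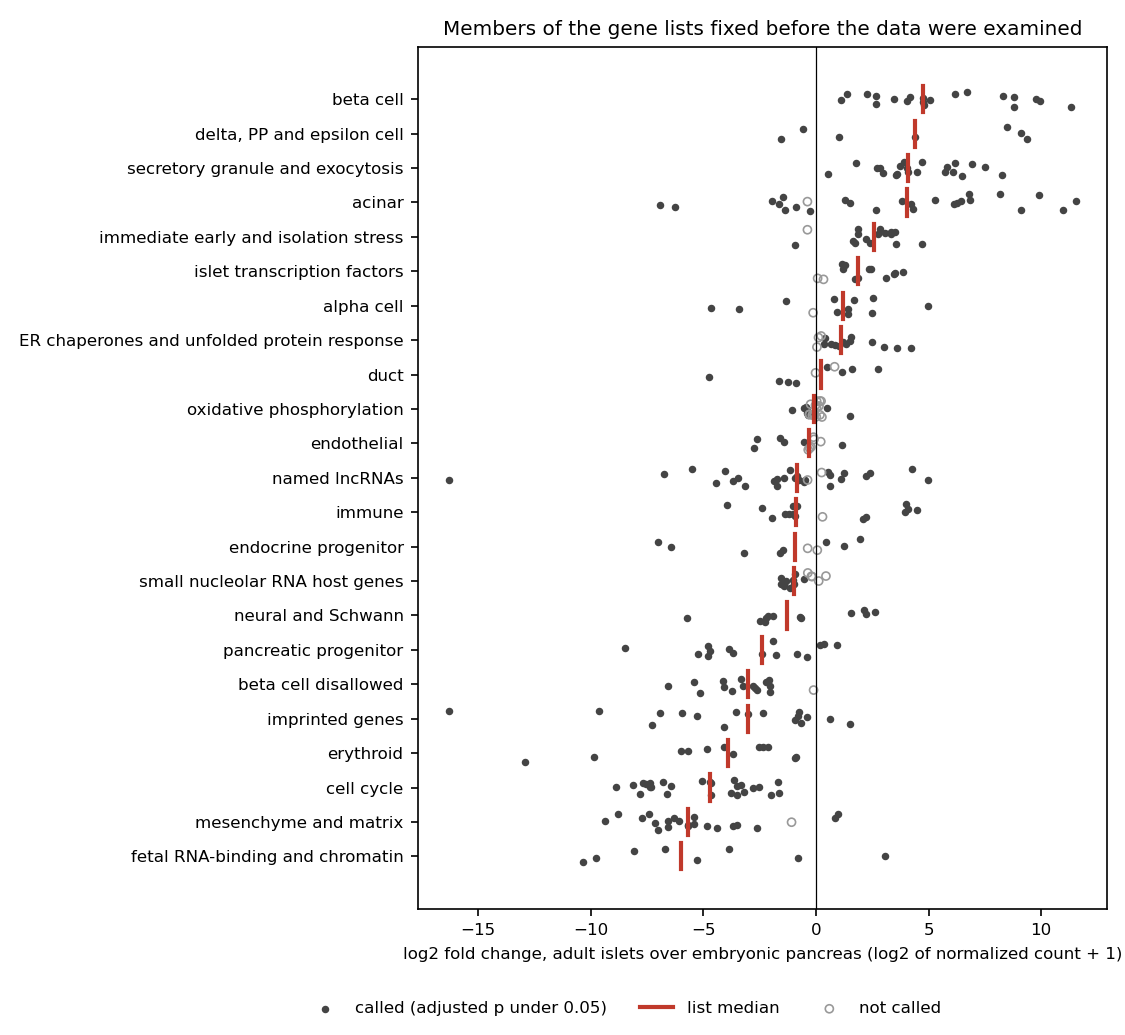
Log2 fold changes (adult islets over embryonic pancreas) of the members of 23 gene lists, sorted by list median (red bar), with filled points for genes called at an adjusted p under 0.05 and open points for the rest. The beta cell list had the highest median, 4.76, and the fetal RNA-binding and chromatin list the lowest, −6.01.

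The lncRNAs with the steepest falls included H19, Xist and 3 lncRNAs transcribed from beside developmental transcription factor genes. H19, an imprinted fetal lncRNA (chromosome 7, 142575529 to 142578143), fell from 128431 ± 13333 to 0.697 ± 0.606, with 2 reads in the islets (ratio 182570, 95% counting interval 50540.4 to 1507550). Xist, which silences an X chromosome (chromosome X, 103460366 to 103483254), fell from 28507 ± 1482 to 31.6 ± 14.6 (log2 fold change −9.89). The sex of the animals is not stated in the labels used here, so a different mix of sexes stays open for Xist. BC006965 (chromosome 11, 112663927 to 112781976) had no reads in the islets and was at least 1309-fold lower there, and Sox9, the progenitor factor gene 0.248 kb away, fell with a log2 fold change of −4.70. Gm16551 (chromosome 9, 74847983 to 74860134) fell from 978 ± 109.8 to 3.06 ± 2.55 (log2 fold change −8.09) and lies 1.79 kb from Onecut1. Wt1os (chromosome 2, 105076538 to 105126510) was at least 187-fold lower, with no reads in the islets, and lies 0.0190 kb from Wt1.

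The 5 steepest rises among lncRNAs were all in transcripts without a functional name. Gm20400 (chromosome 6, 142161493 to 142173796) was at least 568-fold and Gm27168 (chromosome 8, 86920477 to 86921147) at least 390.4-fold higher in the islets, both without reads in the embryonic pancreas. Gm17767 (chromosome 1, 51507086 to 51596718) rose from 5.49 ± 1.21 to 2010.0 ± 319 and D630024D03Rik (chromosome 11, 31790113 to 31824524) from 2.38 ± 2.64 to 494 ± 40.9 (log2 fold changes 8.28 and 7.55). D630024D03Rik had 7 reads over the embryonic libraries, with none in the third, so the size of its rise is uncertain. Gm44850 (chromosome 7, 128215616 to 128220788) rose to 457 ± 113 from 2 reads over the embryonic libraries (ratio 734, 95% counting interval 203 to 6064), and Cox6a2, a cytochrome c oxidase subunit gene 9.23 kb away, rose with a log2 fold change of 8.38. Whether the reads of Gm26917 all come from a lncRNA was not tested. By its annotation it was the most abundant lncRNA of the embryonic pancreas and second to Malat1 in the islets. It averaged 156089 ± 25552 and 113430 ± 10266 and did not pass (log2 fold change −0.45, limma-trend adjusted p = 0.0609). It passed under 8 of the alternatives, where it was lower in the islets, with log2 fold changes from −0.45 to −0.69 under 7 of them and −1.94 under quantile normalization (adjusted p = 9.4e-06). Malat1, a nuclear lncRNA, rose from 64785 ± 18607 to 147766 ± 3375, Gm15564 from 365 ± 131 to 22038 ± 4202 and 2900097C17Rik from 9238 ± 1482 to 15949 ± 1221 (log2 fold changes 1.24, 5.97 and 0.80, that of Malat1 ending at 0.26 and an adjusted p = 0.4998 under quantile normalization), whereas the imprinted lncRNAs Rian and Kcnq1ot1 fell from 35404 ± 2573 to 21046 ± 1777 and from 29931 ± 7669 to 8898 ± 789 (log2 fold changes −0.75 and −1.72).

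Among 2443 lncRNAs tested, 1586 (64.9%) differed by limma-trend, 836 higher and 750 lower, and 1566 did so adjusted over the list alone. The share of higher calls, 52.7%, depended on the processing: it was 64.7% under quantile normalization, with 1069 higher and 582 lower, and the majority turned when scaled without the 20 most abundant genes (726 higher and 859 lower), with no filter (1160 and 1389, 45.5%), by edgeR (789 and 838), by DESeq2 (872 and 944) and without embryonic pancreas 2 (820 and 829). In the authors' deposited table, 868 lncRNAs were higher and 942 lower. Of 608 antisense lncRNAs called, 308 were higher and 300 lower, and of 569 lincRNAs, 329 were higher and 240 lower. Bidirectional promoter lncRNAs were called higher in 65 cases and lower in 10, and sense intronic ones higher in 23 and lower in 73. Strand was not stated to be kept, so reads of antisense and sense intronic lncRNAs and of their host genes cannot be separated, and among the 1319 lncRNAs without exonic overlap 907 (68.8%) differed. Of 29 named lncRNAs with enough reads, 9 rose, 18 fell and 2 were not called, with 27 called adjusted over the list alone. Besides H19, Miat, whose reads are uncertain since it shares 30.4% of its exonic length with another gene, fell from 721 ± 76.0 to 5.99 ± 2.78, while Neat1, the lncRNA of nuclear paraspeckles, rose from 398 ± 125 to 11968 ± 709 (log2 fold changes −6.77 and 4.96). This list did not pass (camera adjusted p = 0.0719), but it did as lower under quantile normalization (0.0412), with no filter (0.0212), by edgeR (0.0246) and by fry (1.6e-04). Of 15 host genes of small nucleolar RNAs, 0 rose, 10 fell and 5 were not called, with 10 called adjusted over the list alone. Snhg18 fell from 668 ± 28.6 to 228 ± 5.06 and Snhg5 from 1445 ± 184 to 493 ± 22.5 (log2 fold changes −1.55 and −1.54), and the list was lower (camera adjusted p = 0.00420, and adjusted p = 0.488 with an estimated correlation).

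The share of genes called at an adjusted p under 0.05 was lower among lncRNAs than among protein-coding genes, but not with at least a 2-fold change. The odds ratio was 0.525 (Fisher's exact test across genes, two-sided, p = 2.4e-41), and genes are not independent replicates. It was 0.813 at a minimum of 50 normalized counts, 0.302 with no filter and 0.210 by DESeq2. With at least a 2-fold change, 1337 of 2443 lncRNAs and 7280 of 15471 protein-coding genes were called, the larger share being that of lncRNAs. The median absolute log2 fold change was 1.18 for lncRNAs and 0.92 for protein-coding genes. At like abundance under a mean log2 value of 8 the order was the reverse. There it was 1.44 for lncRNAs against 2.17 under 5, and 0.97 against 1.67 between 5 and 6. It was 0.85 against 1.64 between 6 and 7 and 0.93 against 1.48 between 7 and 8. Above that lncRNAs had the larger median, 0.90 against 0.84 between 8 and 10 and 0.94 against 0.64 above 10. The median of the mean normalized count was 28.5 for lncRNAs and 768 for protein-coding genes. Within bins of mean log2 value the ratio was 0.631 for genes under 5, 0.492 between 5 and 6, 0.556 between 6 and 7 and 0.475 between 7 and 8, where Fisher's exact test gave adjusted p-values from 9.8e-09 to 4.7e-04. Between 8 and 10 it was 0.743 (Fisher's exact test, adjusted p = 0.242), and above 10, with 29 lncRNAs, it turned to 3.90 (Fisher's exact test, adjusted p = 0.0534).

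Fold changes of lncRNAs correlated with those of the neighbouring protein-coding gene, and the correlation was highest for pairs under 10 kb apart, such as Paupar and Pax6. Across the 2443 lncRNAs and their nearest tested protein-coding gene without overlap, Pearson's r was 0.254 and Spearman's rho 0.250 (permutation p = 1e-04 for each, the smallest that 10000 random pairings can give), and 59.3% of pairs had the same direction. These correlations are across genes, which are not independent replicates. Spearman's rho was 0.423 for the 892 pairs under 10 kb (95% bootstrap interval 0.361 to 0.483), 0.168 for the 740 pairs at 10 to 50 kb and 0.130 for the 811 pairs beyond 50 kb (0.0663 to 0.197). With 1 lncRNA kept per neighbour rho was 0.249 over 2086 pairs. For the 1545 lncRNAs that overlap a protein-coding gene rho was 0.700, where reads of both members cannot be separated. These 1545 are among the 2443 and were not left out of the distance classes. There each was paired with the nearest gene that it does not overlap, so its fold change may carry reads of the overlapped gene.

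**Figure D4:**
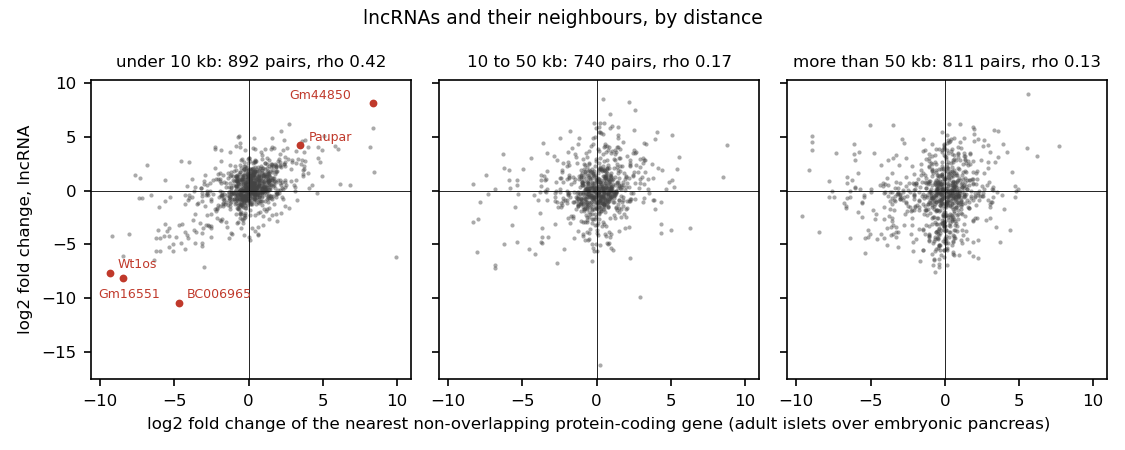
Log2 fold change of each lncRNA (vertical axis) against that of its nearest non-overlapping protein-coding gene (horizontal axis), both adult islets over embryonic pancreas, in 3 classes of distance. Spearman's rho fell from 0.42 over 892 pairs to 0.17 over 740 and 0.13 over 811, and 5 named lncRNAs are marked in red.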

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

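The results in this part were picked after the values were seen, since the reads not assigned to genes stand outside the comparison of genes. In embryonic pancreas 3, 0 reads were set aside for low alignment quality, while the other libraries had 1.89 to 2.50%. Reads aligned to more than 1 place made up 19.4 ± 2.66% of all reads in the adult islets and 14.9 ± 0.724% in the embryonic pancreas (two-sided exact permutation test, p = 0.1, the smallest possible). Reads that fell on more than 1 gene made up 3.74 ± 0.320% in the adult islets and 2.75 ± 0.392% in the embryonic pancreas (exact p = 0.1). For each of the other classes the exact permutation test also gave p = 0.1, so that no class passes 0.05. Reads not aligned made up 8.28 ± 0.386% in the adult islets and 14.7 ± 2.56% in the embryonic pancreas, and reads outside genes 9.87 ± 0.577 and 16.6 ± 4.72%. Reads of low alignment quality made up 2.45 ± 0.0439 and 1.29 ± 1.11%, the latter with embryonic pancreas 3 at 0. For the counts of genes, the 10 ways to split 6 libraries into 3 and 3 are too few for a share under 0.05: the real split called 15770 genes, 1586 lncRNAs and 12050 protein-coding genes by limma-trend, and the highest of the others called 0 (1 split of 10 reached each real count). At an unadjusted p under 0.05 limma-trend gave 16209 genes in the real split and at most 114 genes, 24 lncRNAs and 35 protein-coding genes in the others, on which no other tool was run. By camera the real split called 15 lists, and the others called 11 to 15 (2 splits of 10 reached 15), so that nearly as many lists were called whichever way the libraries were grouped. Without embryonic pancreas 3 and the second islet library, 14033 genes, 1367 lncRNAs and 10746 protein-coding genes were called.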

How the results depend on the processing

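The count models on recovered reads, the fit without 2 libraries and the lncRNAs without exonic overlap were chosen after the data were seen. Leaving out each library in turn gave 14552 to 16460 genes, 1427 to 1649 lncRNAs, 11251 to 12485 protein-coding genes, 15 lists and a lncRNA odds ratio of 0.497 to 0.541. Counts moved by more than 1.5 times for lncRNAs, with 698 at a minimum of 50 normalized counts, 2549 with no filter and 907 without exonic overlap, where the number of genes tested changed, and with at least a 2-fold change, at 10412 genes and 7280 protein-coding genes. The odds ratio was 0.813 at a minimum of 50, 0.302 with no filter and 0.210 by DESeq2, where the number of genes tested also changed. It weakened to 0.743 between log2 values of 8 and 10 and turned to 3.90 above 10, and the cause was not tested. With at least a 2-fold change the share of calls was larger among lncRNAs than among protein-coding genes. With an estimated correlation 0 lists passed: adjusted p was 0.417 for beta, pancreatic progenitor, mesenchyme and disallowed genes, 0.419 for delta, islet transcription factor, ER and stress genes, 0.276 for erythroid, cell cycle and fetal RNA-binding genes, 0.193 for imprinted, 0.289 for granule, 0.488 for small nucleolar host and 0.649 for acinar genes. Each of these is the highest adjusted p over that list's alternatives, the lowest being 2.2e-05 for delta and below 0.001 for the rest. Why the lists missed under this setting was not tested. For the imprinted list the estimated correlation, −0.0455, even lay under the preset 0.01. The delta list also missed at a minimum of 50 (0.0584). By fry the alpha (0.0155, alternatives 0.0155 to 0.708), endocrine progenitor (0.00102, to 0.649), endothelial (0.00947, to 0.649) and named lncRNA (1.6e-04, to 0.419) lists passed. Under quantile normalization endothelial (0.0425), oxidative phosphorylation (0.0109, alternatives to 0.913) and named lncRNA genes (0.0412) passed, the last also with no filter (0.0212) and by edgeR (0.0246). Directions turned for duct (0.989 quantile, 0.95 fry, lowest 0.604, highest 0.992), oxidative phosphorylation (0.899 without embryonic pancreas 2, in a leave-one-out range of 0.250 to 0.899), immune (0.563 edgeR, 0.0187 fry, highest 0.995) and neural lists (0.900 edgeR, 0.757 fry, lowest 0.432), and the cause was not tested. Of 1492 values of named genes under alternatives, 1482 kept direction and side of the threshold; Gm26917 passed in 8, Malat1 missed under quantile normalization (log2 fold change 0.26) and Onecut2 without 2 libraries (0.73). All 23 shares of reads kept their direction in the total without the 20 most abundant genes of each group, the only alternative run, where 3 against 3 libraries cannot give a p under 0.05. All 28 neighbour correlations kept their direction and side. With the replicate number as a block, 15612 genes, 1560 lncRNAs and 11862 protein-coding genes were called; same-numbered libraries deviated with correlations of 0.0369, 0.0775 and 0.00540, so the numbers do not pair them. In simulated libraries of these depths 20 of 50 genes changed 1.5-fold were recovered, a rate that need not hold here, since few simulated genes were changed. The median mean count of lncRNAs was 28.5, but depth alone is not shown to give their lower share of calls, since the odds ratio was 0.475 to 0.631 in bins of like abundance under a log2 value of 8.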

Other observations

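All gene families in this part, the genes named with them and the tests of acinar carry-over, of paralogous enzyme genes, of the Xist level, of the spread of Y and X pairs and of protein-coding pairs under 10 kb were chosen after the results were seen. Most antigen presentation and interferon-induced genes were higher in the adult islets. Of 18 MHC class I and II genes, 15 rose and 0 fell (median log2 fold change 3.42, camera adjusted p = 2.8e-05, and adjusted p = 0.314 with an estimated correlation), among them H2-K1, from 776 ± 131 to 21642 ± 2107. Of 37 interferon-induced genes, 25 rose and 2 fell (camera adjusted p = 2.4e-04, and adjusted p = 0.845 with an estimated correlation), among them Ifit1, at 3139, 2644 and 876 in the islet libraries against 17.9 ± 2.61 in the embryonic pancreas. Of 15 synaptotagmin genes, whose products trigger vesicle fusion, 11 rose and 2 fell (camera adjusted p = 0.00127, and adjusted p = 0.314 with an estimated correlation), with Syt4 going from 86.6 ± 12.2 to 15841 ± 898 and Syt13 from 2651 ± 745 to 41717 ± 3837.

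Hox genes and most collagen and ribosomal protein genes were lower in the islets. Of 21 Hox genes, which set position along the body axis, 0 rose and 21 fell (camera adjusted p = 5.5e-07, and adjusted p = 0.314 with an estimated correlation), for example Hoxc5 from 228 ± 37.8 to 1.42 ± 0.674. Of 45 collagen genes, 7 rose and 37 fell (camera adjusted p = 4.8e-08, and adjusted p = 0.318 with an estimated correlation). Of 80 cytosolic ribosomal protein genes, 0 rose and 73 fell, by a median log2 of −0.95 (camera adjusted p = 1.8e-10, and adjusted p = 0.776 with an estimated correlation). Of 14 Sox genes, 0 rose and 12 fell, and of 18 Wnt and Frizzled genes, 1 rose and 14 fell (camera adjusted p = 4.3e-04 and 0.00110, and adjusted p = 0.531 and 0.314 with an estimated correlation). Of 65 potassium channel genes, 29 rose and 25 fell (camera adjusted p = 0.643), with Kcnj6 rising from 3.37 ± 0.637 to 300.1 ± 25.8 and Kcnd3 falling from 510.5 ± 44.8 to 35.9 ± 6.02. A further 12 families, among them calcium and sodium channels, Fox genes, keratins and proteasome subunits, did not pass.

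Outside the lists, and also picked after the values were seen, the mitochondrial leucyl-tRNA synthetase gene Lars2 went from 2338 ± 763 to 184637 ± 41006 (log2 fold change 6.34) and the unclassified transcript Gm38070 from 132 ± 31.7 to 23892 ± 4169 (log2 fold change 7.5). Whether the reads counted for Lars2 all come from its messenger RNA was not tested, so a rise of that RNA is not shown.

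Of 26 acinar genes, 17 were higher in islets that had been freed from the surrounding tissue with collagenase, with Pnlip at 109899, Cela1 at 89917, Ctrb1 at 74473 and Prss2 at 68490 normalized counts there. Reads shared between paralogs are argued against, since the 13 members without a near-identical copy had a median log2 fold change of 4.23, with 8 of them called higher. Acinar cells carried along with the islets cannot be told apart from other sources, because the library with the highest acinar share was picked for the test: the second islet library exceeded the mean of the other 2 by a median log2 of 1.15 over the list (SD 0.576 over members, 24 of 26 above 0), against −0.161 for the beta cell list. Of the 26 members 0 belong to another list, and 25 reached 10 normalized counts in every embryonic library, so that the embryonic pancreas expresses them too. An untested difference of age and tissue, such as more enzyme RNA per adult acinar cell, stays open, as Rbpjl and Prss1 fell by 6.91 and 6.26 on the log2 scale while Pnlip rose. More RNA per acinar cell would still need acinar cells among the islets, so it is not an alternative to their being carried along.

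Xist fell and 3 of 4 Y-linked genes rose in the islets, Ddx3y from 2656 ± 383 to 5501 ± 224, Uty from 1604 ± 290.4 to 3440.4 ± 351 and Eif2s3y from 1257 ± 53.6 to 3433 ± 96.8, while Kdm5d was not called (1746 ± 228 to 2023 ± 15.3, adjusted p = 0.0817). Regulation with tissue or age at an equal sex ratio is argued against by the level of Xist in the islets, 0.111% of that in the embryonic pancreas. A different mix of sexes stays open, since the Y-linked gene exceeded its X-linked partner beyond the spread in 3 of 4 pairs but not for Kdm5d: the median log2 difference was 1.39, with 1.35 (95% interval 0.751 to 1.95) for Ddx3y, 1.44 (0.813 to 2.06) for Uty, 1.60 (1.10 to 2.10) for Eif2s3y and 0.09 (−0.257 to 0.435) for Kdm5d. Sex is not stated in the labels used here, so how far it adds to differences in other genes stays open.

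Fold changes of neighbouring lncRNA and protein-coding genes correlated, weakly over all distances (rho 0.250, 59.3% of pairs in the same direction) and more under 10 kb (rho 0.423, 66.4%). No lncRNA was left out of these pairs for overlapping another protein-coding gene, whose reads cannot be separated from its own. For the 568 lncRNAs under 10 kb before the 5′ end of the neighbour, rho was 0.463 (0.391 to 0.530). Reads running past the 3′ end of the neighbour do not fall there and are argued against for these pairs. For the 324 lncRNAs under 10 kb past the 3′ end, rho was 0.337 (0.225 to 0.452, difference 0.126, −0.0180 to 0.250), and such reads stay open. Reads of a lncRNA that run into the neighbour were not tested. Beyond 50 kb, reads past the end of the neighbour cannot be told apart, because the interval of the rho of 0.130 (0.0663 to 0.197) reaches under the 0.1 set beforehand. Under 10 kb, protein-coding pairs had a rho of 0.155, lower by 0.268 (0.205 to 0.333). They were not split by side of the neighbour, and lay a median of 2.21 kb apart against 1.27 kb for the lncRNA pairs. With pairs not matched in this way, a like change of any neighbouring genes cannot be told apart there. Over all distances, where protein-coding pairs had a rho of 0.135, it cannot be told apart, because the lower bound of the difference of 0.115 (0.0733 to 0.158) lies under the 0.1 set beforehand, and beyond 50 kb the protein-coding pairs had a rho of 0.0884 (difference 0.0414, −0.0377 to 0.124). Shared promoters, unannotated 5′ ends of the neighbour and an untested difference of age and tissue stay open for the close pairs, of which BC006965 with Sox9, Wt1os with Wt1 and, with the reads of Onecut1 uncertain, Gm16551 with Onecut1 may be examples.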
